A study of Homo sapiens with 21 samples.

How the data were processed

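The series holds 21 whole-transcript gene arrays of the human embryonic stem cell line H7, treated with BMP4 and sampled on 7 days with 3 arrays per day, as given in the sample labels. Total RNA was extracted with TRIzol and labelled with a kit for whole transcripts, per the labels. The values deposited by the authors are log2 signals made by robust multi-array averaging (RMA), per the submitters' processing notes, a method that corrects background, quantile-normalizes the probes and summarises them per transcript. No software version is stated, nor whether all 21 arrays were normalized together. The range and medians of the values are those of RMA log2 data, and no further transformation was applied. Arrays have no read depth, so their number, 3 per day, limits the precision.

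The table has 33297 transcript clusters, of which 19460 carry exactly 1 gene symbol in the platform's probe table. Their Entrez identifiers were looked up in a gene table of assembly GRCh38.p14, used for names only, and 19429 were found there with 0 symbols to update. Another 1754 clusters list several genes and 12083 are not in the probe table, and none of these is named. For the 769 genes with more than 1 cluster, the cluster with the highest mean over all arrays was taken, which left 18417 genes. POU5F1, NANOG, CGB5, CSH1, HLA-G and SOLD1 had no cluster of their own and are not analysed here.

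One linear model with a mean per day was fitted to all 21 arrays with limma 3.58.1 in R 4.3.3 (14 residual degrees of freedom, prior 9.8). Each later day was compared with day 0, and each day with the day sampled 2 days earlier, which gave 11 comparisons, and a moderated F test asked whether a gene differed between any days. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p below 0.05. Calls that also differed by at least 1 on the log2 scale were counted as changed 2-fold. Comparisons that share day 0 also share its 3 arrays and are not independent. A gene was counted as transient when it rose from day 0 to a day from 2 to 10 and fell from that day to day 12, both called, and the count was repeated on 20 simulated data sets.

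The 25 gene lists cover pluripotency, trophoblast transcription factors, syncytiotrophoblast and placental hormones, extravillous trophoblast, epithelial keratins and junctions, mesenchymal and matrix genes, amnion, BMP targets and inhibitors, primitive streak and mesoderm, endoderm, neural ectoderm, cardiac and smooth muscle, endothelial and blood cells, proliferation, DNA methylation enzymes, antigen presentation, interferon response, glycolysis and hypoxia, cholesterol, steroid hormone synthesis, imprinted genes, immediate early and stress genes, the WNT, FGF and NODAL pathways, and ribosomal proteins. They hold 632 measured genes, of which 23 are in more than 1 list. Each list was tested with limma's camera with a preset correlation of 0.01, adjusted over the 25 lists of a comparison (275 tests in all), and again with a correlation estimated from the data, which allows for genes that move together. Members called up and down were counted from the adjustment over all genes and, separately, adjusted over the list alone.

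Named genes follow a rule. For each comparison it takes the 8 largest rises and the 8 largest falls among called genes whose 3 arrays of one day all lie above the 3 of the other, a separation that chance gives 10% of genes and for which an exact test has a smallest two-sided p of 0.1. It adds up to 4 called members per list with the largest change, a fixed set of stem cell, trophoblast, amnion and mesenchymal markers, and the 8 leading transient genes. Gene lists, tests, the naming rule and the alternative settings were fixed before the data were examined.

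The procedure was tested on simulated data made for day 2 against day 0 with 18417 genes and 50 changed genes per size. It recovered 72% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, 2 or 4, with 10 false calls among 196 (5.1%) and 0 calls in a comparison without change. Camera called the list that had been shifted and 0 of 20 lists that had not. The simulated noise was independent between genes, whereas the correlation estimated for the ribosomal list was 0.423. The simulation therefore does not show how camera with the preset correlation behaves for lists whose genes move together.

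The alternative settings fixed in this way were a replicate block, a fit to only the 6 arrays compared, leaving out the 30% of genes with the lowest mean, the mean of a gene's clusters, all clusters tested one by one, centring each array on its median, quantile normalization of the deposited values, a variance prior with an intensity trend, array weights, leaving out each array in turn, and camera with an estimated correlation. A fit with the array median as a covariate, and one without the arrays day 6 replicate 3 and day 8 replicate 1, were chosen after the data had been seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.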

Results

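Cells of the human embryonic stem cell line H7, kept on irradiated mouse embryonic fibroblast feeders, were cultured with bone morphogenetic protein 4 (BMP4), a growth factor used to direct such cells toward trophoblast, the outer cell lineage of the placenta. Total RNA was profiled on whole-transcript gene arrays on days 0, 2, 4, 6, 8, 10 and 12, with 3 arrays per day and 21 arrays in all. The series' design text speaks of 10 days of sampling, while the sample labels run to day 12. The labels name no batch, so differences of day 12 from other days cannot be told apart from a separate culture or run. Signals are log2 values from robust multi-array averaging (RMA) for 18417 named genes, and the array medians over these genes lay between 7.8 and 7.9. Across all transcript clusters, which are not independent replicates, correlations between arrays of the same day ran from 0.989 to 0.995, and the arrays' lower quartiles from 5.9 to 6.1. Signals below these quartiles were not shown to be above background, so changes from or to such levels are lower bounds. Gene values below are the mean log2 signal ± SD with n = 3 arrays per day, changes are differences of these means on the log2 scale, and adjusted p values for genes come from limma. The series holds no untreated samples of the later days, so changes between days cannot be assigned to BMP4 rather than to time in culture. The labels do not say whether the 3 arrays of a day come from separate cultures, so the limma p values measure the spread between these samples. Camera p values compare the genes of a list with all other genes.

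Over the whole course the cells lost stem cell transcripts in steps. They gained transcripts of the epithelial, amnion and trophoblast lists up to days 6 to 10. Many of these were lost again between days 10 and 12, when matrix transcripts were at their highest. On day 6 the median changes against day 0 were 0.80 for epithelial genes, 0.82 for amnion genes and 0.55 for trophoblast transcription factors. Which lineage the cells belonged to was not tested. SOX2, a core pluripotency factor, went from 9.14 ± 0.27 on day 0 to 6.85 ± 0.20 on day 10, and LIN28A, an RNA-binding protein of stem cells, from 12.37 on day 0 to 9.54 on day 12. KRT7, a simple-epithelium keratin of trophoblast, went from 7.66 ± 0.24 on day 0 to 12.20 ± 0.18 on day 6 and back to 8.33 ± 0.16 on day 12. Between-day differences were called for 11022 of 18417 genes by limma's moderated F test (59.8%), and 2699 of these had day means at least 1 log2 unit apart. The first 4 principal components of the arrays held 41.7, 22.9, 11.1 and 6.7% of the variance.

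A rise followed by a fall was a common course. Of all genes, 2639 rose from day 0 to a peak between days 2 and 10 and then fell to day 12, each by limma's adjusted p, and 422 of these moved by at least 1 log2 unit both ways. In 20 simulated data sets in which no gene changed on any day the highest count was 0 for both. A count near 0 was to be foreseen there, so the simulations give no chance level for genes that do change. Day 6 was the peak of 211 of the 422, day 10 of 77, day 4 of 72, day 8 of 37 and day 2 of 25. Ranked by the smaller of rise and fall, ITGB6, GRHL2, CDH1 and KRT7 came first, while no gene list was tested among the transient genes. ITGB6, an epithelial integrin subunit that is in the amnion list, rose by 4.79 to day 6 and fell by 4.52 to day 12. CDH1, which encodes E-cadherin, rose by 3.89 and fell by 4.63, KRT7 rose by 4.55 and fell by 3.87, and GRHL2, a transcription factor of epithelial cells, rose by 4.15 and fell by 3.91. MUC15, a membrane mucin abundant in placenta, peaked on day 10 after a rise of 5.55 and then fell by 3.62.

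**Figure D1:**
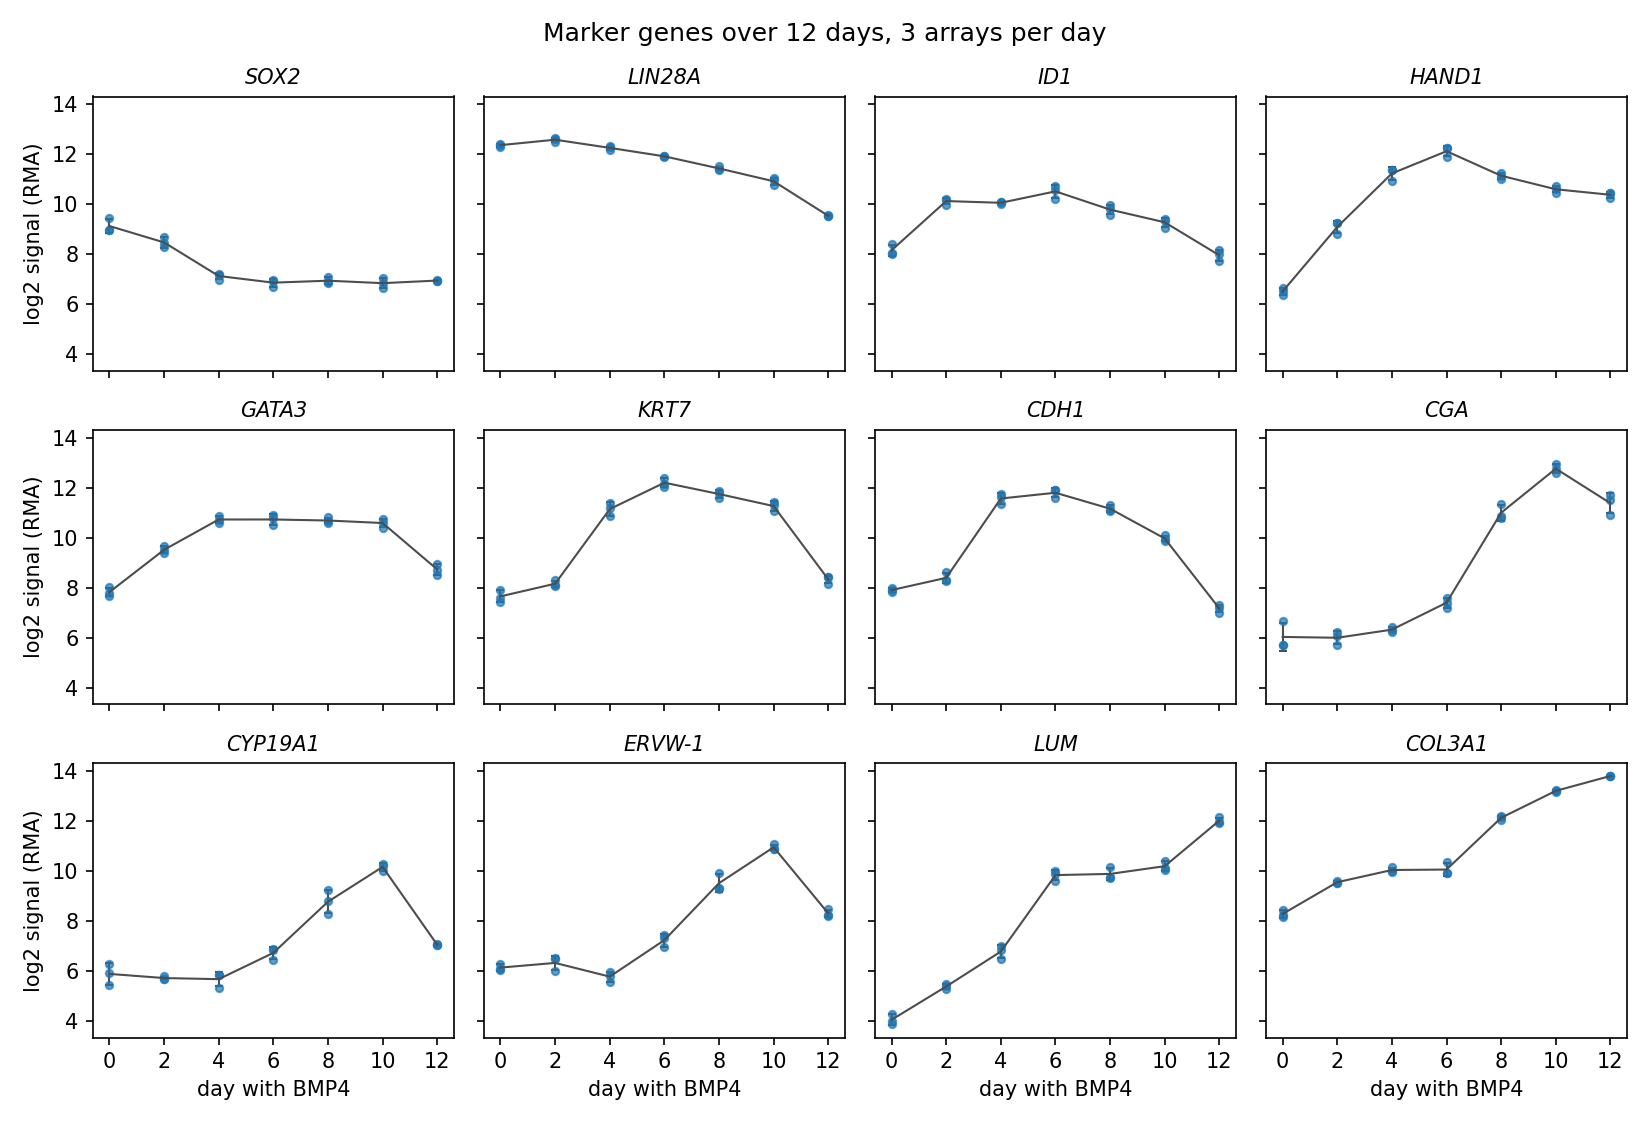
Log2 RMA signal of 12 genes against the day with BMP4, where points are single arrays, lines join the day means and bars are the SD of 3 arrays. CDH1 and KRT7 were highest on day 6, CGA, CYP19A1 and ERVW-1 on day 10, and LUM and COL3A1 on day 12.

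The number of genes that changed at least 2-fold differed between the 2-day steps. It was 159 up and 114 down from day 0 to day 2, 174 up and 85 down to day 4, 182 up and 68 down to day 6, and 74 up and 32 down to day 8. The later steps had 78 up and 18 down to day 10, and 156 up and 350 down to day 12. With any 1 array left out the falls ranged from 24 to 37 in the step to day 8, from 11 to 25 in the step to day 10 and from 300 to 386 in the step to day 12. Without day 6 replicate 3 and day 8 replicate 1, which stood apart from their days, the step to day 8 had 63 up and 61 down, and with arrays weighted by quality 70 and 50. The step to day 12 had the most 2-fold falls of the 6 steps.

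**Figure D2:**
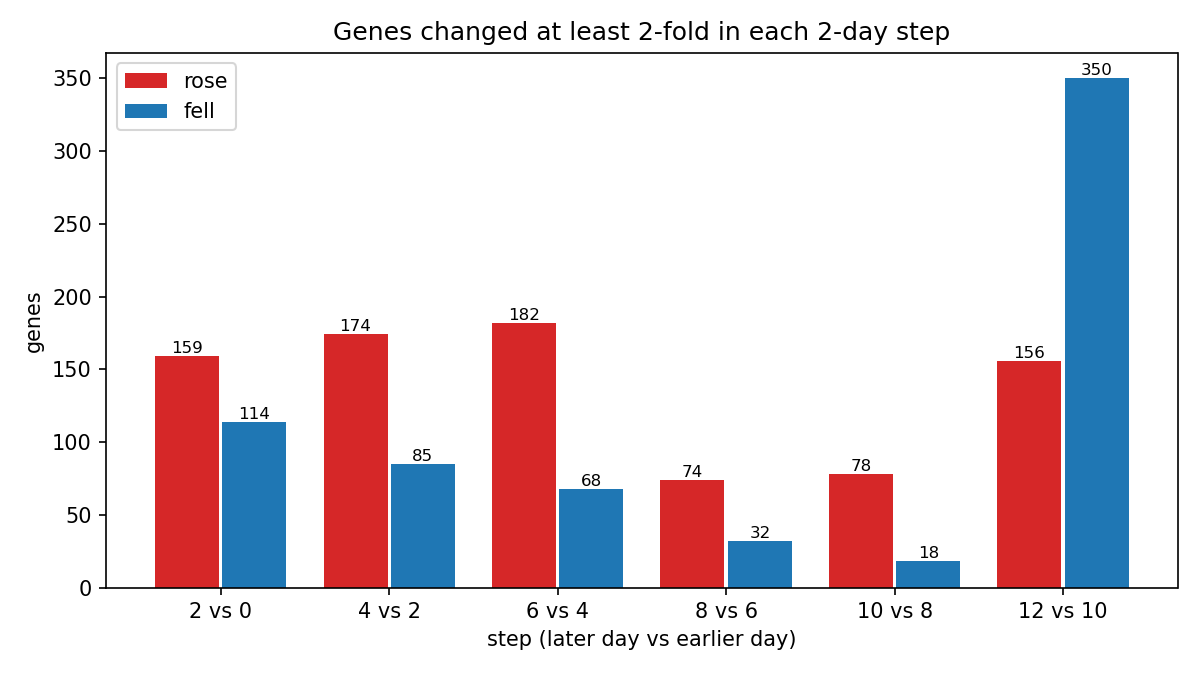
Bars give the number of genes that rose or fell at least 2-fold in each 2-day step among those with a limma adjusted p below 0.05. The step from day 10 to day 12 holds 350 falls, against 18 in the step before it (300 to 386 and 11 to 25 with 1 array left out).

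Day 2 against day 0 covers the first 2 days with BMP4. Known BMP targets were higher: MSX2, a homeobox gene induced by BMP, went from 8.01 ± 0.05 to 11.14 ± 0.15 (adjusted p = 2.83e-16). BAMBI, a decoy receptor that restrains BMP signalling, went from 9.03 ± 0.01 to 11.82 ± 0.10 (adjusted p = 4.35e-17), and ID1, an inhibitor of differentiation factors, from 8.17 ± 0.22 to 10.14 ± 0.13. Some trophoblast regulators rose with them, although their list as a whole went both ways (camera adjusted p = 0.174). HAND1 rose by 2.58 to 9.10 ± 0.25, TFAP2A by 2.54 to 8.68 ± 0.15 and GATA3 by 1.69 to 9.52 ± 0.13. CER1, a secreted antagonist of NODAL and BMP, had the largest fall, from 11.66 ± 0.24 to 7.49 ± 0.22 (adjusted p = 8.18e-16).

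In that first step, 17 of 24 measured BMP targets and inhibitors rose and 1 fell (19 and 2 adjusted over the list alone), with a median change of 1.19. Camera gave this list an adjusted p of 2.36e-18 (adjusted p = 0.00722 with an estimated correlation). Matrix genes followed, with 20 of 33 up and 3 down (21 and 3 adjusted over the list alone, camera adjusted p = 3.48e-11, and adjusted p = 0.194 with an estimated correlation). POSTN rose by 2.67, COL1A2 by 2.23 and FN1, fibronectin, by 1.65. Of 41 cell division genes 14 rose and 2 fell (17 and 3 adjusted over the list alone, camera adjusted p = 0.00455, and adjusted p = 0.7 with an estimated correlation). TOP2A rose by 0.77 and KIF20A by 0.85. The endoderm list fell with 6 of 25 members down and 1 up (6 and 1 adjusted over the list alone), led by CER1, which stem cells themselves expressed on day 0 (camera adjusted p = 0.0191, and adjusted p = 0.194 with an estimated correlation). Among 17 endothelial genes 3 fell and 0 rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.0409, and adjusted p = 0.644 with an estimated correlation).

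Some stem cell genes had changed by day 2, but their list was not called as a set. Of 32 measured pluripotency genes 7 fell and 2 rose (the same counts adjusted over the list alone), SOX2 changed by −0.66 and LEFTY2, an antagonist of NODAL, by −1.09, and the list's camera adjusted p was 0.194. Trophoblast transcription factors went both ways, 10 of 38 up and 6 down (11 and 8 adjusted over the list alone, camera adjusted p = 0.174), with a median change of 0.00 and a mean of 0.32. In all, limma called 4028 of 18417 genes between day 0 and day 2, 2377 up and 1651 down.

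The step from day 2 to day 4 asks which program followed the first response. Epithelial genes rose strongly: EPCAM, an epithelial adhesion molecule, went from 8.81 ± 0.36 to 12.11 ± 0.26, CDH1 from 8.40 ± 0.20 to 11.57 ± 0.20, KRT7 from 8.16 ± 0.12 to 11.15 ± 0.27 and GRHL2 from 6.85 ± 0.12 to 10.16 ± 0.20. The largest measured rise was that of ATP12A, a proton pump subunit, by 3.71, followed by DIO3, which inactivates thyroid hormone, by 3.44 and the prolactin receptor PRLR by 3.39. USP44, a ubiquitin protease of stem cells, fell by 1.96, and SOX2 fell by 1.34.

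Of 30 measured epithelial keratin and junction genes 20 rose and 1 fell from day 2 to day 4 (20 and 1 adjusted over the list alone), with a median change of 0.57. The camera adjusted p was 3.9e-17 (adjusted p = 0.0256 with an estimated correlation). Trophoblast transcription factors rose in 19 of 38 and fell in 2 (20 and 3 adjusted over the list alone, camera adjusted p = 1.07e-10, and adjusted p = 0.0568 with an estimated correlation). HAND1 rose by 2.14. The amnion list, whose members also mark early surface ectoderm and trophoblast, had 8 of 19 up and 3 down (10 and 4 adjusted over the list alone, camera adjusted p = 3.76e-06, and adjusted p = 0.0698 with an estimated correlation). ISL1 rose by 2.36 and VTCN1 by 1.91. Cholesterol genes rose in 12 of 18 and fell in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 2.05e-09, and adjusted p = 0.0993 with an estimated correlation). HMGCS1, which makes the precursor HMG-CoA, rose by 1.09 and DHCR7, which catalyses the last step, by 0.82. The primitive streak list had 9 of 29 up and 1 down (10 and 1 adjusted over the list alone, camera adjusted p = 0.000988, and adjusted p = 0.389 with an estimated correlation). TBXT, the gene that defines the streak, rose by 0.43 to 7.42 ± 0.15.

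Other groups fell from day 2 to day 4. Ribosomal protein genes fell in 19 of 38 (26 adjusted over the list alone) and rose in 0, and RPL11 fell by 0.52 (camera adjusted p = 2.55e-06, and adjusted p = 0.389 with an estimated correlation). Immediate early and stress genes fell in 20 of 29 and rose in 0 (20 and 1 adjusted over the list alone), with a camera adjusted p of 4.05e-09 (adjusted p = 0.0759 with an estimated correlation). SESN2, a stress-induced growth brake, fell by 1.16, and the p53 regulator MDM2 fell by 1.01. Cell division genes fell in 15 of 41 and rose in 0 (19 and 1 adjusted over the list alone, camera adjusted p = 5.37e-05, and adjusted p = 0.488 with an estimated correlation). Matrix genes fell in 16 of 33 and rose in 5 (17 and 6 adjusted over the list alone, camera adjusted p = 0.0102, and adjusted p = 0.491 with an estimated correlation). Glycolysis genes fell in 11 of 27 and rose in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00982, and adjusted p = 0.491 with an estimated correlation).

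The day 4 arrays had a narrower spread of signal than the other days, with a mean distance between quartiles of 2.72 against 2.85 on day 2 and 2.89 on day 6. This coincided with the falls of the bright ribosomal and stress genes. After quantile normalization the medians of these lists were −0.13 and −0.30, against −0.30 and −0.45 as deposited. Limma called 4855 genes in this step, 1425 up and 3430 down, so 70.6% of the calls were falls (59.6% after quantile normalization and 74.9% after centring each array).

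From day 4 to day 6 further stem cell transcripts went down, epithelial genes rose further, and several placental hormone transcripts rose. MIR302A, a microRNA gene of stem cells, went from 6.93 ± 0.24 to 4.25 ± 0.35, and CRIPTO, a NODAL co-receptor, fell by 1.44. HSD3B1, the placental enzyme that makes progesterone, went from 7.33 ± 0.30 to 9.68 ± 0.19, ERVW-1, which encodes the fusion protein syncytin-1, rose by 1.46 and CGA, the alpha subunit of chorionic gonadotropin, by 1.08. LUM, which encodes the matrix proteoglycan lumican, had the largest measured rise, from 6.78 ± 0.26 to 9.84 ± 0.20.

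Of 32 pluripotency genes 9 fell and 1 rose in this step (9 and 2 adjusted over the list alone), with a camera adjusted p of 0.000684 (adjusted p = 0.0162 with an estimated correlation). The epithelial list rose in 18 of 30 and fell in 0 (18 and 0 adjusted over the list alone, camera adjusted p = 5.41e-05, and adjusted p = 0.263 with an estimated correlation). KRT7 rose by 1.06. Amnion genes rose in 12 of 19 and fell in 2 (12 and 3 adjusted over the list alone, camera adjusted p = 0.000123, and adjusted p = 0.132 with an estimated correlation). ITGB6 rose by 2.75 and VTCN1 by 1.75. Trophoblast transcription factors rose in 17 of 38 and fell in 6 (19 and 7 adjusted over the list alone, camera adjusted p = 0.0362, and adjusted p = 0.558 with an estimated correlation). EPAS1, a hypoxia-responsive factor, rose by 1.89 while TFAP2C fell by 0.96. This list's call was lost with centred arrays (adjusted p = 0.0586). The syncytiotrophoblast list had 11 of 38 up and 0 down at this step (11 and 0 adjusted over the list alone), while its median change was 0.00, its mean 0.23 and its camera adjusted p 0.26.

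Ribosomal and stress genes went back up from day 4 to day 6. Ribosomal protein genes rose in 28 of 38 and fell in 0 (31 and 0 adjusted over the list alone, camera adjusted p = 5.45e-09, and adjusted p = 0.373 with an estimated correlation). RPL11 rose by 0.73. Immediate early and stress genes rose in 15 of 29 and fell in 2 (16 and 2 adjusted over the list alone, camera adjusted p = 3.1e-07, and adjusted p = 0.132 with an estimated correlation). SESN2 rose by 1.23. These rises coincided with the return of the quartile distance from 2.72 on day 4 to 2.89 on day 6. Antigen presentation genes fell in 2 of 13 (2 adjusted over the list alone) and rose in 0 (camera adjusted p = 0.0362, and adjusted p = 0.132 with an estimated correlation). Limma called 4426 genes, 3114 up and 1312 down. The balance depended on scaling and on the arrays, with 2623 up and 1616 down after quantile normalization and 3679 and 978 after centring each array. It was 4437 up and 2514 down, 6951 in all, with arrays weighted by quality, and 4038 and 2248 without day 6 replicate 3 and day 8 replicate 1.

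Between day 6 and day 8 syncytiotrophoblast genes, those of the fused hormone-producing layer of the placenta, rose. CGA rose by 3.60 from 7.40 ± 0.20 (adjusted p = 1.84e-11), ERVW-1 went from 7.24 ± 0.26 to 9.51 ± 0.37 and CYP19A1, the aromatase that makes estrogens, from 6.73 ± 0.23 to 8.77 ± 0.47. GCM1, a transcription factor that drives trophoblast fusion, rose by 1.29 to 8.14. Fibrillar collagen rose in the same step, with COL3A1 going from 10.06 ± 0.25 to 12.13 ± 0.08.

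Syncytiotrophoblast genes rose in 16 of 38 and fell in 1 from day 6 to day 8 (17 and 1 adjusted over the list alone), with a camera adjusted p of 5.38e-14 (adjusted p = 2.16e-05 with an estimated correlation). Matrix genes rose in 18 of 33 and fell in 0 (21 and 0 adjusted over the list alone, camera adjusted p = 1.83e-27, and adjusted p = 0.00652 with an estimated correlation). Their median change was 0.49, and COL6A3 rose by 1.92. Steroid hormone genes rose in 5 of 22 and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00923, and adjusted p = 0.0406 with an estimated correlation). CYP11A1, which starts steroid synthesis from cholesterol, rose by 1.81. Endothelial genes rose in 3 of 17 and fell in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.00122, and adjusted p = 0.179 with an estimated correlation). The vascular receptors KDR rose by 1.32 and TEK by 1.26.

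Falls in this step covered pluripotency, cholesterol and epithelial genes. Pluripotency genes fell in 10 of 32 and rose in 0 (13 and 0 adjusted over the list alone, camera adjusted p = 3.33e-06, and adjusted p = 0.000705 with an estimated correlation). L1TD1, an RNA-binding protein of stem cells, fell by 1.23. Cholesterol genes fell in 12 of 18 and rose in 0 (14 and 0 adjusted over the list alone, camera adjusted p = 4.15e-12, and adjusted p = 0.0477 with an estimated correlation). HMGCS1 fell by 0.96. Epithelial genes fell in 11 of 30 and rose in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 3.33e-06, and adjusted p = 0.129 with an estimated correlation). EPCAM fell by 0.97. Amnion genes fell in 8 of 19 and rose in 1 (10 and 2 adjusted over the list alone, camera adjusted p = 1.6e-05, and adjusted p = 0.0521 with an estimated correlation). Cell division genes fell in 5 of 41 and rose in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 1.74e-06, and adjusted p = 0.319 with an estimated correlation). Camera also called the BMP list, with 4 of 24 down and 0 up (6 and 2 adjusted over the list alone, adjusted p = 0.0472), and the imprinted list, with 4 of 25 up and 1 down (4 and 1 adjusted over the list alone, adjusted p = 0.0472). Neither call held with centred arrays, at adjusted p values of 0.0542 and 0.0534. Immediate early genes were up in 5 of 29 and down in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0148), while of 38 ribosomal protein genes 0 were called either way, although camera called the list (adjusted p = 0.00915). These 4 lists had an adjusted p between 0.211 and 0.543 with an estimated correlation.

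Limma called 1327 genes between day 6 and day 8, 646 up and 681 down, and with 1 array left out from 525 to 677 up and from 417 to 1035 down. Day 6 replicate 3 and day 8 replicate 1 stood apart from the other arrays of their days, with quartile distances of 2.77 against 2.94 and 2.95 on day 6, and of 2.96 against 2.80 and 2.79 on day 8. With both left out 3596 genes were called, with arrays weighted by quality 5313, and with only these 6 arrays in the fit 752.

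From day 8 to day 10 hormone genes rose further and epithelial genes fell further. CGA rose by 1.76 to 12.76 ± 0.17, CYP19A1 rose from 8.77 ± 0.47 to 10.16 ± 0.16, and ERVFRD-1, which encodes syncytin-2, from 8.29 to 9.91. SST, which encodes the peptide hormone somatostatin, had the largest measured rise, from 9.84 to 12.37. The matrix proteoglycan DCN went from 5.19 ± 0.08, below the lower quartile, to 7.63 ± 0.28, so the order of both rises is not certain. CDH1 fell from 11.16 ± 0.13 to 9.97 ± 0.12, and EPCAM fell by 1.15.

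Syncytiotrophoblast genes rose in 18 of 38 and fell in 1 from day 8 to day 10 (19 and 1 adjusted over the list alone), with a camera adjusted p of 1.51e-14 (adjusted p = 1.71e-05 with an estimated correlation). Steroid hormone genes rose in 9 of 22 and fell in 0 (9 and 1 adjusted over the list alone, camera adjusted p = 9.14e-06, and adjusted p = 0.00154 with an estimated correlation). CYP11A1 rose by 1.62. Matrix genes rose in 19 of 33 and fell in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 2.37e-24, and adjusted p = 0.00799 with an estimated correlation). POSTN rose by 1.66. Antigen presentation genes rose in 3 of 13 and fell in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.00299, and adjusted p = 0.0169 with an estimated correlation). B2M, the light chain of HLA class I, went from 9.48 to 10.24. Imprinted genes rose in 5 of 25 and fell in 1 (7 and 2 adjusted over the list alone, camera adjusted p = 0.000329, and adjusted p = 0.0175 with an estimated correlation). DLK1 rose by 2.16. Interferon-induced genes rose in 4 of 26 and fell in 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.00195, and adjusted p = 0.0629 with an estimated correlation). IFIT1 rose by 1.53.

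Epithelial genes fell in 14 of 30 and rose in 1 in that step (20 and 2 adjusted over the list alone), with a camera adjusted p of 1.27e-12 (adjusted p = 0.0169 with an estimated correlation). Pluripotency genes fell in 9 of 32 and rose in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.000263, and adjusted p = 0.00357 with an estimated correlation). Cell division genes fell in 16 of 41 and rose in 0 (26 and 0 adjusted over the list alone, camera adjusted p = 4.43e-14, and adjusted p = 0.116 with an estimated correlation). The replication factors CDC6 and MCM5 changed by −0.51 and −0.42. The BMP list fell with 7 of 24 down and 2 up (10 and 3 adjusted over the list alone, camera adjusted p = 0.00386, and adjusted p = 0.258 with an estimated correlation). Among endothelial genes 3 of 17 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0127, and adjusted p = 0.258 with an estimated correlation). Limma called 1565 genes, 873 up and 692 down, and with 1 array left out from 655 to 950 up and from 392 to 793 down. The count was 2564 with arrays weighted by quality.

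Between day 10 and day 12 trophoblast, epithelial and hormone genes fell together while several matrix genes rose. KRT7 went from 11.27 ± 0.19 to 8.33 ± 0.16, CDH1 from 9.97 ± 0.12 to 7.17 ± 0.15, CYP19A1 from 10.16 ± 0.16 to 7.05 ± 0.03 (adjusted p = 4.55e-12) and ERVW-1 from 10.95 ± 0.10 to 8.30 ± 0.16. TFAP2C, a trophoblast transcription factor, fell by 2.55 and GCM1 fell by 2.04. DCN, by contrast, went from 7.63 ± 0.28 to 11.36 ± 0.15 (adjusted p = 3.1e-17), LUM rose by 1.82 to 12.02, and STC1, a secreted glycoprotein hormone, rose by 3.11.

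Epithelial genes fell in 22 of 30 and rose in 1 from day 10 to day 12 (22 and 1 adjusted over the list alone), with a median change of −0.96. The camera adjusted p was 8.74e-20 (adjusted p = 0.00492 with an estimated correlation). Trophoblast transcription factors fell in 22 of 38 and rose in 1 (23 and 1 adjusted over the list alone, camera adjusted p = 9.95e-13, and adjusted p = 0.013 with an estimated correlation). GATA3 fell by 1.86. Syncytiotrophoblast genes fell in 16 of 38 and rose in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 1.23e-08, and adjusted p = 0.000442 with an estimated correlation). CGA fell by 1.38 and was still at 11.38 ± 0.41. Extravillous trophoblast genes, those of the invasive cell type, fell in 14 of 27 and rose in 0 (16 and 0 adjusted over the list alone, camera adjusted p = 2.5e-08, and adjusted p = 0.00492 with an estimated correlation). ADAM19 fell by 1.72. Steroid hormone genes fell in 9 of 22 and rose in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00222, and adjusted p = 0.013 with an estimated correlation). HSD3B1 changed by −2.49 and CYP11A1 changed by −2.54.

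Stress, glycolysis and BMP genes fell in the same step. Immediate early and stress genes fell in 19 of 29 and rose in 0 (20 and 0 adjusted over the list alone, camera adjusted p = 4.05e-13, and adjusted p = 0.0137 with an estimated correlation). Glycolysis genes fell in 18 of 27 and rose in 3 (19 and 4 adjusted over the list alone, camera adjusted p = 8.73e-07, and adjusted p = 0.181 with an estimated correlation). The glucose transporters SLC2A3 and SLC2A1 changed by −2.09 and −1.45. BMP targets and inhibitors fell in 11 of 24 and rose in 0 (13 and 1 adjusted over the list alone, camera adjusted p = 6.47e-05, and adjusted p = 0.102 with an estimated correlation). MSX2 changed by −1.66 and the antagonist NOG changed by −1.70. Amnion genes fell in 7 of 19 and rose in 1 (8 and 2 adjusted over the list alone, camera adjusted p = 0.000555, and adjusted p = 0.102 with an estimated correlation), and ISL1 fell by 2.02. Genes of the WNT, FGF and NODAL pathways fell in 12 of 33 and rose in 3 (12 and 4 adjusted over the list alone, camera adjusted p = 0.0251, and adjusted p = 0.102 with an estimated correlation).

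Rises to day 12 covered antigen presentation, matrix and division genes. Antigen presentation genes rose in 5 of 13 and fell in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 0.00265, and adjusted p = 0.016 with an estimated correlation). B2M rose by 1.12 and the peptide-trimming enzyme ERAP1 by 0.91. Matrix genes rose in 16 of 33 and fell in 7 (18 and 7 adjusted over the list alone, camera adjusted p = 0.00254, and adjusted p = 0.369 with an estimated correlation). Cell division genes rose in 15 of 41 and fell in 3 (16 and 3 adjusted over the list alone, camera adjusted p = 0.00182, and adjusted p = 0.481 with an estimated correlation). MKI67 rose by 0.57. The primitive streak list rose with 6 of 29 up and 2 down (6 and 2 adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.369 with an estimated correlation). HAND2, which rose by 1.44, and PDGFRA, which rose by 1.25, are also genes of heart and connective tissue. Cholesterol genes were up in 7 of 18 and down in 3, and interferon-induced genes up in 5 of 26 and down in 1, with the same counts adjusted over the list alone. Camera gave each an adjusted p of 0.0493, against an adjusted p = 0.51 and an adjusted p = 0.227 with an estimated correlation. The cholesterol call was lost with centred arrays (adjusted p = 0.0573) and with a replicate block (adjusted p = 0.0576). Limma called 4241 genes, 1742 up and 2499 down. The mean quartile distance of the arrays was 2.84 on day 10 and 2.75 on day 12.

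Day 4 against day 0 covers the first 4 days as a whole. HAND1 was higher by 4.72, CDH1 went from 7.91 ± 0.09 to 11.57 ± 0.20, and TFAP2A and KRT7 were higher by 3.65 and 3.49. SOX2 went from 9.14 ± 0.27 to 7.14 ± 0.12, while CER1 changed by −4.16 and TFPI2, an inhibitor of serine proteases, by −3.64. BMP genes were up in 18 of 24 and down in 2 (19 and 2 adjusted over the list alone, camera adjusted p = 8.1e-15, and adjusted p = 0.0184 with an estimated correlation). Epithelial genes were up in 18 of 30 and down in 4 (19 and 4 adjusted over the list alone, camera adjusted p = 4.29e-10). Trophoblast transcription factors were up in 19 of 38 and down in 7 (21 and 8 adjusted over the list alone, camera adjusted p = 4.37e-08), and cholesterol genes up in 13 of 18 and down in 0 (16 and 0 adjusted over the list alone, camera adjusted p = 1.21e-09). Each of these 3 lists had an adjusted p = 0.093 with an estimated correlation. Ribosomal protein genes were down in 25 of 38 and up in 0 (26 and 0 adjusted over the list alone, camera adjusted p = 2.71e-06, and adjusted p = 0.462 with an estimated correlation), on the arrays with the quartile distance of 2.72. Limma called 5780 genes, 2224 up and 3556 down.

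Day 6 against day 0 took in the day on which the largest number of transient genes peaked. HAND1 was at its highest, 12.13 ± 0.20 against 6.52 ± 0.15, and KRT7 was higher by 4.55, ITGB6 by 4.79 and EPAS1 by 4.75. The stem cell microRNA gene MIR302B was lower by 4.08 and the BMP antagonist GREM1 fell by 3.72. Epithelial genes were up in 23 of 30 and down in 2 (23 and 2 adjusted over the list alone, camera adjusted p = 3.72e-14, and adjusted p = 0.0135 with an estimated correlation). Trophoblast transcription factors were up in 26 of 38 and down in 6 (26 and 6 adjusted over the list alone, camera adjusted p = 5.93e-11, and adjusted p = 0.0229 with an estimated correlation), and amnion genes up in 12 of 19 and down in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 5.93e-11, and adjusted p = 0.01 with an estimated correlation). Pluripotency genes were down in 14 of 32 and up in 4 (16 and 4 adjusted over the list alone, camera adjusted p = 8.26e-05, and adjusted p = 0.00603 with an estimated correlation). Endothelial genes, which the starting cells expressed in part, were down in 5 of 17 and up in 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.00424, and adjusted p = 0.282 with an estimated correlation). ESAM, an endothelial adhesion molecule, fell by 2.09. Limma called 5417 genes, 2966 up and 2451 down.

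Day 8 against day 0 showed the hormone genes above their starting level. CGA was higher by 4.97, ERVW-1 by 3.38 and CYP19A1 by 2.89, and CRIPTO was lower by 3.38. Syncytiotrophoblast genes were up in 15 of 38 and down in 5 (16 and 5 adjusted over the list alone, camera adjusted p = 0.000908, and adjusted p = 0.0141 with an estimated correlation). Pluripotency genes were down in 19 of 32 and up in 2 with a median change of −0.54 (19 and 2 adjusted over the list alone, camera adjusted p = 3.22e-09, and adjusted p = 0.000139 with an estimated correlation). Trophoblast transcription factors were up in 23 of 38 and down in 6 (25 and 6 adjusted over the list alone, camera adjusted p = 1.79e-10, and adjusted p = 0.0266 with an estimated correlation). Matrix genes were up in 25 of 33 and down in 6 (25 and 6 adjusted over the list alone, camera adjusted p = 4.01e-11, and adjusted p = 0.0578 with an estimated correlation). Limma called 5887 genes, 3093 up and 2794 down.

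Day 10 against day 0 is the endpoint of the 10-day period in the design text. CGA had the largest measured rise, from 6.03 ± 0.56 to 12.76 ± 0.17 (a log2 change of 6.73, adjusted p = 3.64e-18), followed by LUM from 4.05 ± 0.21 to 10.19 ± 0.19. The day 0 signals lay at the lower quartile of the arrays for CGA and far below it for LUM, so these rises are lower bounds and their order is not certain. Syncytin-1, aromatase and the steroid enzymes were far above their starting level, with ERVW-1 higher by 4.81, CYP11A1 by 4.38, CYP19A1 by 4.28 and HSD3B1 by 4.09. Trophoblast regulators stayed high, with HAND1 up by 4.09, TBX3 by 3.46, TFAP2A by 2.78, GATA3 by 2.76, GCM1 by 2.45 and GATA2 by 1.64. Among stem cell genes, CRIPTO changed by −4.03, USP44 by −3.40, SOX2 by −2.29, and the microRNA genes MIR302A and MIR302B by −4.39 each.

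Several genes often read as trophoblast or mesoderm markers had little or no change by day 10. CDX2, an early trophoblast factor, was higher by 0.09 (adjusted p = 0.533) after a rise of 0.47 by day 4 (adjusted p = 0.00037). ELF5, a factor of trophoblast stem cells, differed by −0.16 (adjusted p = 0.347), PSG1, a pregnancy-specific glycoprotein, by −0.07 (adjusted p = 0.829) and the primitive streak factor TBXT by −0.11 (adjusted p = 0.482). With the array median as a covariate ELF5 was called, at −0.53. EOMES, a factor of mesendoderm and of mouse trophoblast, fell from 8.30 to 7.59. VIM, the mesenchymal filament gene, differed by −0.11 (adjusted p = 0.409), while COL1A1 was higher by 1.02.

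By list, pluripotency genes were down in 22 of 32 and up in 2 on day 10 against day 0 (23 and 2 adjusted over the list alone), with a median change of −0.81. The camera adjusted p was 5.54e-11 (adjusted p = 3.81e-05 with an estimated correlation). Syncytiotrophoblast genes were up in 17 of 38 and down in 3 (17 and 3 adjusted over the list alone, camera adjusted p = 6.15e-07, and adjusted p = 0.00081 with an estimated correlation). Steroid hormone genes were up in 10 of 22 and down in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.000506, and adjusted p = 0.00872 with an estimated correlation). Trophoblast transcription factors were up in 23 of 38 and down in 6 (23 and 7 adjusted over the list alone, camera adjusted p = 3.2e-08, and adjusted p = 0.0409 with an estimated correlation). Matrix genes were up in 25 of 33 and down in 3 with a median change of 1.49 (25 and 3 adjusted over the list alone, camera adjusted p = 6.2e-18, and adjusted p = 0.025 with an estimated correlation). Amnion genes were up in 12 of 19 and down in 2 (camera adjusted p = 1.14e-05), BMP genes up in 16 of 24 and down in 3 (camera adjusted p = 5.7e-08), with the same counts adjusted over the list alone. Each had an adjusted p = 0.0409 with an estimated correlation. Epithelial genes were up in 16 of 30 and down in 5 (17 and 5 adjusted over the list alone, camera adjusted p = 0.000261, and adjusted p = 0.239 with an estimated correlation). Extravillous genes were up in 12 of 27 and down in 5 (12 and 5 adjusted over the list alone, camera adjusted p = 0.0453, and adjusted p = 0.264 with an estimated correlation).

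Cell division genes were down in 24 of 41 and up in 1 on day 10 (24 and 2 adjusted over the list alone, camera adjusted p = 6.11e-06, and adjusted p = 0.391 with an estimated correlation). Imprinted genes were up in 12 of 25 and down in 5 (12 and 5 adjusted over the list alone, camera adjusted p = 0.0169, and adjusted p = 0.121 with an estimated correlation), and immediate early genes up in 14 of 29 and down in 4 (15 and 4 adjusted over the list alone, camera adjusted p = 0.00651, and adjusted p = 0.391 with an estimated correlation). Lists of other lineages were not called as sets on day 10 against day 0. Endoderm genes were up in 6 of 25 and down in 3 (6 and 4 adjusted over the list alone, camera adjusted p = 0.57), and neural genes up in 1 of 25 and down in 8 (camera adjusted p = 0.117). Cardiac and smooth muscle genes were up in 7 of 21 and down in 4 (camera adjusted p = 0.57), and endothelial genes up in 4 of 17 and down in 2 (camera adjusted p = 0.964). Blood genes were up in 1 of 14 and down in 1 (camera adjusted p = 0.961), and primitive streak genes up in 7 of 29 and down in 4 (camera adjusted p = 0.2). The same held for WNT, FGF and NODAL pathway genes, with 8 of 33 up and 13 down (9 and 13 adjusted over the list alone, camera adjusted p = 0.215), and for glycolysis genes, with 8 of 27 up and 10 down (camera adjusted p = 0.396). Of 38 ribosomal protein genes 0 were up and 4 down (0 and 2 adjusted over the list alone, camera adjusted p = 0.57). DNA methylation genes were up in 2 of 12 and down in 6 (camera adjusted p = 0.158), with the demethylation enzyme TET2 higher by 1.52 while the methyltransferase DNMT3B fell by 1.02. Antigen presentation genes were up in 4 of 13 and down in 2 (camera adjusted p = 0.57), interferon-induced genes up in 7 of 26 and down in 2 and cholesterol genes up in 5 of 18 and down in 0 (camera adjusted p = 0.158 for both). For lists given without a count adjusted over the list alone, that count equals the one over all genes. The median and the mean change had opposite signs for the cardiac (−0.01 and 0.10), endothelial (−0.04 and 0.02), primitive streak (−0.03 and 0.39) and antigen presentation lists (−0.03 and 0.18), and both were near 0 for the endoderm, blood and ribosomal lists. In all, limma called 6892 genes between day 10 and day 0, 3529 up and 3363 down.

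**Figure D3:**
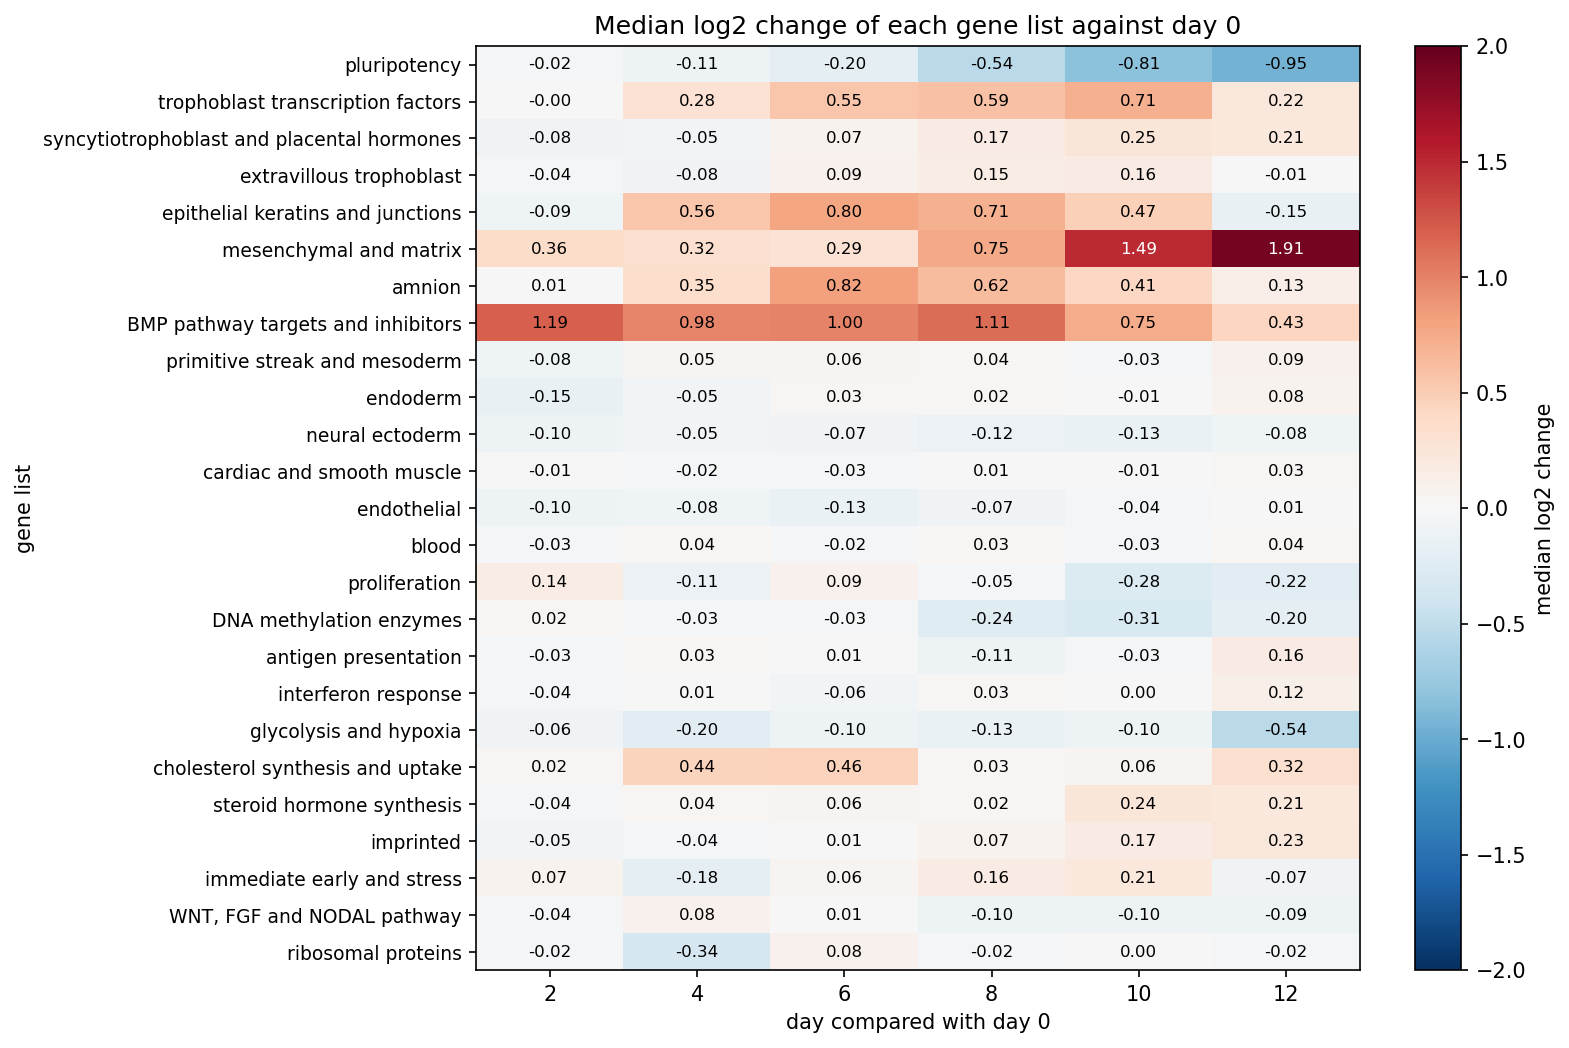
Heat map of the median log2 change against day 0 of the measured members of 25 gene lists, with days 2 to 12 across and lists down. The matrix list reached 1.91 and the pluripotency list −0.95 on day 12, while the epithelial list went from 0.80 on day 6 to −0.15 on day 12.

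Day 12 against day 0 describes cells with fewer stem cell transcripts and more matrix transcripts. LUM was higher by at least 7.97 at 12.02 ± 0.12 and DCN by at least 6.61, both from signals below the lower quartile. COL3A1 was higher by 5.52 and COL6A3 by 5.35, and SST went from 7.90 to 13.72. CGA was still higher by 5.35 and HAND1 by 3.87, whereas KRT18 differed by −0.03 (adjusted p = 0.896), ID1 by −0.20 (adjusted p = 0.261) and VTCN1 by −0.31 (adjusted p = 0.198). With arrays weighted by quality ID1 (−0.28) and VTCN1 (−0.39) were called, and so was VTCN1 without day 12 replicate 3 (−0.49). SPP1, which encodes osteopontin, fell from 12.30 to 7.01, and CRIPTO changed by −4.60, LIN28A by −2.83 and TFAP2C by −2.01. All samples were grown on mouse feeders per the labels, and whether mouse RNA adds to the signals was not tested.

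Pluripotency genes were down in 24 of 32 and up in 2 on day 12 (24 and 3 adjusted over the list alone, camera adjusted p = 2.76e-10, and adjusted p = 5.64e-05 with an estimated correlation). Matrix genes were up in 24 of 33 and down in 5 (24 and 5 adjusted over the list alone, camera adjusted p = 3.83e-13, and adjusted p = 0.135 with an estimated correlation). Epithelial genes were down in 12 of 30 and up in 6 (12 and 6 adjusted over the list alone, camera adjusted p = 0.0404, and adjusted p = 0.512 with an estimated correlation). Trophoblast transcription factors were up in 15 of 38 and down in 8 (17 and 8 adjusted over the list alone, camera adjusted p = 0.0861). Syncytiotrophoblast genes were up in 13 of 38 and down in 6 (14 and 6 adjusted over the list alone, camera adjusted p = 0.0454, and adjusted p = 0.142 with an estimated correlation). Glycolysis genes were down in 18 of 27 and up in 4 (18 and 5 adjusted over the list alone, camera adjusted p = 0.000394, and adjusted p = 0.467 with an estimated correlation), and SLC2A3 fell by 2.97. Imprinted genes were up in 12 of 25 and down in 4, DCN being one of the list (13 and 4 adjusted over the list alone, camera adjusted p = 0.0255, and adjusted p = 0.142 with an estimated correlation). Interferon-induced genes were up in 10 of 26 and down in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0255, and adjusted p = 0.157 with an estimated correlation). Antigen presentation genes were up in 6 of 13 and down in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0504), with B2M higher by 3.03. Centring the arrays or a replicate block brought this list under the threshold (adjusted p = 0.0428 and adjusted p = 0.0474).

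Camera also called pathway, primitive streak, division and cholesterol lists on day 12. WNT, FGF and NODAL pathway genes were down in 16 of 33 and up in 8 (16 and 8 adjusted over the list alone, camera adjusted p = 0.0308, and adjusted p = 0.142 with an estimated correlation), with FGFR2 higher by 3.84. BMP genes were up in 13 of 24 and down in 7 (13 and 7 adjusted over the list alone, camera adjusted p = 0.0308, and adjusted p = 0.467 with an estimated correlation). Primitive streak genes were up in 9 of 29 and down in 4 (9 and 4 adjusted over the list alone, camera adjusted p = 0.0454, and adjusted p = 0.512 with an estimated correlation). TBX20, higher by 4.94, and PDGFRA, higher by 4.07, are genes of developing heart and connective tissue. Cell division genes were down in 20 of 41 and up in 10 (21 and 10 adjusted over the list alone, camera adjusted p = 0.0454, and adjusted p = 0.653 with an estimated correlation), and with centred arrays the adjusted p was 0.0523. Cholesterol genes were up in 9 of 18 and down in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0206, and adjusted p = 0.506 with an estimated correlation). The other 11 lists had camera adjusted p values between 0.0594 and 0.92, the lowest for amnion genes, which were called with centred arrays (adjusted p = 0.0486). Limma called 7790 genes, 3805 up and 3985 down. Over all 11 comparisons, camera called 114 of 275 list tests with its preset correlation and 42 with an estimated correlation.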

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

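The tests of a lower trophoblast share and of diluted stem cells were chosen after the results they address had been seen. The other tests of causes also address patterns first seen in these data, so they were planned ahead only of their own results. The regrouping of the arrays was chosen before.

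Between day 10 and day 12, 60 members of the trophoblast transcription factor, syncytiotrophoblast and epithelial lists fell, with a median log2 change of −1.23, while 16 of 33 matrix genes rose and 7 fell, a rise that is not called with an estimated correlation (camera adjusted p = 0.369). With each array left out in turn the median of these 60 kept at least 97.6% of its size, and under other scalings at least 101.6%. They were chosen as called falls, which needs arrays that agree, so leaving out arrays does not decide on a stray array. Over all measured members the list medians were, in the order above, −0.52, −0.22 and −0.96. After quantile normalization they were −0.48, −0.24 and −0.97, which argues against scale differences left in the deposited values as the cause of the falls. Such differences were small, with gene medians of the day 10 and day 12 arrays between 7.87 and 7.91, so rescaling could change little. Effects of the scaling within RMA cannot be seen this way. A lower share of trophoblast cells with no other change would raise the genes of all other cells alike. Over all members the matrix list had a median of 0.225 and a mean of 0.324, and the cardiac and smooth muscle list a median of 0.039 and a mean of −0.205 (permutation test of the means, p = 0.043). This test exchanges genes between the lists, so its p does not measure the spread between samples. Since both medians were above 0 and the cardiac genes went both ways, 2 up and 6 down of 21, the lower share stays open. A change of state in the cells that expressed these genes and a change in the signal of the mouse feeder cells stay open too and were not tested. The labels name no batch, and the design text covers 10 days only. A separate culture or run of the day 12 samples therefore cannot be told apart from the day.

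Epithelial genes were low on day 0 and rose by day 4, with CDH1 going from 7.91 ± 0.09 to 11.57 ± 0.20 (SD, n = 3), although stem cell colonies are usually epithelial. Scaling left at least 97% of the median change of the members that rose, and leaving out any single array at least 93.2%. These members were chosen as called rises, which needs arrays that agree, so leaving out arrays does not decide on a stray array. Over all measured epithelial members the median change was 0.56 as deposited, 0.53 with centred arrays and 0.57 after quantile normalization. These medians argue against scale differences left in the deposited values. Such differences were small, with gene medians of the day 0 and day 4 arrays between 7.80 and 7.86, so rescaling could change little. Effects of the scaling within RMA cannot be seen this way. Had other cells diluted the stem cells on day 0, bright stem cell genes would have risen too, and 11 pluripotency genes with a mean signal of at least 9 had a median change of −0.11 (range −2.45 to 0.43). Dilution stays open all the same: 4 of the 11 fell by more than 0.25, and a loss of stem cell transcripts under BMP4 would hide such a rise. A change in the cells after BMP4 was added, and a starting culture that already held cells with few epithelial transcripts, stay open and were not tested.

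From day 2 to day 4 falls made up 70.6% of the genes called. A shift of whole arrays is argued against, since the share was 74.9% after centring each array. A different distribution of values on the day 4 arrays stays open as part of the cause: after quantile normalization the share was 59.6%, and among the 3430 genes that fell 2510 still fell. Compression of bright signals stays open too, with falls in 37% of the calls among the dimmest genes, 61.9% among those in the middle and 84% among the brightest, in 3 groups of equal size by mean signal. Of the genes called after quantile normalization 1766 rose, so the balance between rises and falls in this step depends on how the arrays were scaled, and a biological cause was not tested.

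Probe clusters that list several genes, which no comparison uses, also gave a signal: 22 of 1754 rose at least 2-fold and 50 fell from day 0 to day 10. Among the 12083 clusters outside the probe table, 79 rose at least 2-fold and 184 fell over the same days. From day 10 to day 12, 3 clusters with several genes rose and 13 fell. In that step 57 clusters outside the probe table rose and 40 fell.

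Each count was compared with those of other groupings of the arrays. For a comparison of 2 days every other split mixes arrays of both days. A real difference between the days then adds to the spread and cancels in part, so low counts there were to be foreseen. For 10 of the 11 comparisons only 1 of the 10 splits of the 6 arrays, the real one, called any genes, and the highest other count was 0, as for day 2 against day 0 with 4028 calls and day 12 against day 10 with 4241. The 10 splits are too few for a share under 0.05, and because of this mixing they give no chance level. The real counts of the others were 5780, 5417, 5887, 6892 and 7790 against day 0 (days 4, 6, 8, 10 and 12), 4855 for day 4 against day 2, 4426 for day 6 against day 4, and 1565 for day 10 against day 8. Day 8 against day 6 differed: 2 of its 10 splits called at least the real 1327 genes, and the highest other, which exchanges day 6 replicate 3 and day 8 replicate 1, called 4739, which points to a structure of the samples. For the F test 1 of 100 splits, the real one, reached 11022 genes and the highest other 1570. A random assignment of the arrays to days is argued against there. Arrays of a day that share a culture would give the same result, so this does not separate day from culture.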

How the results depend on the processing

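The fits with the array median as a covariate and without day 6 replicate 3 and day 8 replicate 1 were chosen after seeing the data; all other alternatives were planned. No gene result that passed the threshold changed direction, nor did a list result under centring, the replicate block or an estimated correlation, the settings in which lists were tested again, and the total counts of genes called stayed within 1.5 times the reported ones except in the following cases. From day 6 to day 8 (1327 genes) the count was 752 with only the 6 arrays compared, 5313 with array weights and 3596 without the pair of arrays; array weights gave 6951 from day 4 to day 6 (4426) and 2564 from day 8 to day 10 (1565). The balance of rises and falls among the calls was less stable. Over all settings the share of falls ran from 36.6 to 47.4%, 54.2 to 67%, 41.9 to 50.8%, 44.6 to 52.2%, 46.9 to 52.7% and 49.7 to 56.2% against day 0 (days 2 to 12; reported fits 41, 61.5, 45.2, 47.5, 48.8 and 51.2%), and from 59.6 to 75%, 21 to 38.1%, 43.6 to 62.8%, 30.1 to 51.8% and 54.7 to 64.4% for the later steps (70.6, 29.6, 51.3, 44.2 and 58.9%). After centring or quantile normalization 33 of 275 list medians differed in sign, all of them 0.11 or less in size and 0 of them from lists that camera called. The cause was not tested. An estimated correlation left 42 of 114 list calls. The estimates were 0.423 for the ribosomal list, 0.403 for cell division and 0.252 for matrix genes, against the preset 0.01, while pluripotency genes had −0.003. A higher correlation widens the spread that camera allows for a list. The preset p values are therefore too small for lists whose genes move together. With the replicate block the counts against day 0 were 4210, 5990, 5617, 6051, 7053 and 7984 (days 2 to 12), the steps 5096, 4652, 1451, 1696 and 4440 (days 4 to 12), the F test 11223 and the list calls 114, although residuals of arrays that share a number correlated by a median of only 0.02 (63 pairs, −0.35 to 0.54), against −0.02 for different numbers. With 1 array left out in turn the counts ranged from 3208 to 4290, 4810 to 6079, 4603 to 5717, 5058 to 6136, 6091 to 7142 and 7023 to 8062 against day 0 (days 2 to 12), from 3597 to 5227, 3053 to 5512, 945 to 1683, 1085 to 1743 and 3416 to 4554 for the later steps, and from 10541 to 11784 for the F test. For the 1251 gene results, 7193 refits with 1 array left out gave the reported call, 305 missed the threshold and 8 passed it newly. Under the other settings 39 gene results missed it and 0 passed newly with all clusters tested, 33 and 4 with the covariate, 21 and 1 with centring, 16 and 1 with quantile normalization, 34 and 3 with only 6 arrays, 9 and 12 with weights, 16 and 5 without the pair, 0 and 2 without the dimmest 30% of genes, 0 and 1 with the replicate block and 1 and 0 with the intensity trend. Centring moved 5 list calls above the threshold and 4 below it, and the block 2 each way. Signal over background limits what can be read for dim genes.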

Other observations

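The first 2 paragraphs describe genes chosen after their values had been seen. Among the tests, the one for exchanged labels was chosen after the result it addresses, and the list of amino acid response genes was drawn up after ASNS and its neighbours had been noticed. The test for a compressed range likewise addresses a pattern first seen in these data.

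Several genes of developmental transcription factors were higher on day 12. HOXD10, a homeobox gene of the posterior limb, went from 6.50 on day 0 to 7.36 on day 6 and 10.56 on day 12 (adjusted p = 4.5e-19), HOXD11 from 7.28 to 9.22, and HOXB13 from 7.20 to 9.12. Of 27 measured HOX genes 17 were called up on day 12 against day 0, 5 of them at least 2-fold, and 0 were called down, against 3805 of all 18417 genes called up and 750 at least 2-fold; the HOX genes were not tested as a set. MEIS1, a partner of HOX proteins, rose by 4.31, and TBX4, a factor of the hindlimb bud and of the allantois, the mesoderm that forms the umbilical vessels, went from 7.42 to 8.99 on day 6 and 11.01 on day 12. GATA4, a factor of heart and endoderm, went from 8.14 to 10.48, and TBX20, a heart mesoderm factor, from 7.44 to 12.38.

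ANKRD1, CCN1 and CCN2, which are targets of YAP, a coactivator that responds to cell shape and tension, were lower on day 12, while YAP targets were not tested as a set. ANKRD1 stood between 12.32 and 13.54 from day 0 to day 10 and at 9.03 on day 12. CCN1 went from 11.28 on day 0 to 9.95 on day 10 and 8.46 on day 12, and CCN2 from 12.77 to 10.94 and 9.45. POU5F1B, a gene similar in sequence to the stem cell factor POU5F1, went from 9.36 on day 0 to 10.10 on day 4 and 7.53 on day 8. Whether its probes also read POU5F1 was not tested.

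Enzymes of amino acid supply went up and down together, with ASNS, the asparagine synthetase, at 9.02 on day 0, 11 on day 2, 10.55 on day 4, 11.17 on day 6, 10.58 on day 10 and 8.55 on day 12, and PSAT1, an enzyme of serine synthesis, on these days at 10.15, 11.05, 9.56, 10.96, 10.28 and 8.19. A shared amino acid response was tested on 20 other measured genes of that response over 4 steps, in the directions that ASNS took. They moved in its direction in 4 of 4 steps: 15 rose by day 2 (median 0.54, camera adjusted p = 5.28e-12), 18 fell by day 4 (−0.65, camera adjusted p = 2.29e-13), 15 rose by day 6 (0.67, camera adjusted p = 6.27e-12), and 13 fell and 1 rose from day 10 to day 12 (−0.56, camera adjusted p = 5.33e-09), with adjusted p between 0.0276 and 0.0451 with an estimated correlation. After quantile normalization the medians were 0.51, −0.51, 0.51 and −0.55. Neighbouring steps share the arrays of day 2 or day 4, and the directions were read from ASNS on the same arrays, so the 4 results are not independent. The steps from day 6 to day 8 and from day 8 to day 10 were not tested. Synthetases for transfer RNA outside the response, 6 measured, had medians of −0.16, −0.28, 0.25 and −0.17, with camera adjusted p of 0.064, 0.0622, 0.0506 and 0.122. These synthetases thus went the other way by day 2 and the same way, less far, in the other steps tested. The swings may reflect the amino acid response, whether from medium changes or from culture density, which was not tested.

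Day 6 replicate 3 and day 8 replicate 1 lay apart from the other arrays of their days, on a component that held 32.3% of the variance within days. On an axis from day 4 to day 10 built from 671 genes without the arrays of days 6 and 8, day 6 lay at 0.33, 0.31 and 0.30 and day 8 at 0.73, 0.67 and 0.69. So 0 of the pair lay nearer the other day, which argues against an exchange of the labels of the pair. A compressed range of values on some arrays stays open: after quantile normalization the split that exchanges the pair called 1744 genes, 36.8% of the 4739 before, so part of the difference may come from the range of the signals.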
